A study of Glycine max with 3 samples.

How the data were processed

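The series holds 3 RNA-seq libraries from seeds of the soybean (Glycine max) cultivar Asgrow A3237, each made from 1 tissue region cut out of paraffin sections by laser capture microdissection. The globular-stage embryo gave the embryo proper and the suspensor libraries, and the seed coat parenchyma library came from seeds at early maturation. Per the labels' protocols, embryos were taken from pods 0.5 to 1.2 cm long and seed coats from seeds 6.0 to 7.0 mm long. The embryo regions were cut from sections of 6 µm and the seed coat from sections of 8 µm, on different microdissection instruments. Between 3 and 5 ng of total RNA was converted to cDNA and amplified with a whole-transcriptome kit before adapters were ligated, and the ligated product went through 15 further PCR cycles. Reads were single-end and 76 nt long.

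The authors deposited 1 table per library, which per the file headers gives for each gene model a count of mapped reads. The values are whole numbers whose totals differ between libraries, so they were treated as raw counts. The aligner Bowtie is named in the submitters' processing notes. Its version, the genome build, the annotation release, the handling of reads with several equally good hits and the use of strand are not given in the sources used here. Because the soybean genome carries many near-identical duplicated genes, the unknown handling of such reads leaves the counts of close paralogs uncertain, and reads from overlapping genes on opposite strands cannot be told apart. The counts are of reads, not of molecules, since no molecular identifiers were used, so counting intervals and detection floors cover counting error only and leave out amplification and tissue variation.

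All 3 tables list the same 66210 gene models, of which 65781 carry the number of 1 of the 20 chromosomes in their name and 429 the number of an unplaced scaffold. Every table line names a gene model. The tables pair no identifier with a gene name. The reference table used here (59048 genes of assembly Glycine_max_v4.0) matched 0 of the 66210 identifiers by identifier, locus tag, synonym, symbol or accession. The 42 lists of functional gene groups and cell type markers that had been fixed before the data were examined rest on product names, and therefore none of them could be tested. For the same reason no gene name, coordinate, exon or function is given. At most 2 identifiers per direction are printed in each comparison, and the only positional information is the chromosome number and the order of gene models that the soybean naming scheme puts into the identifier.

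The labels give 1 library per region and name no replicate. No p-value, standard error or differential expression call is therefore given, and every difference describes these libraries and has no replicate check. Counts were scaled with edgeR (version 4.0.16 in R 4.3.3) TMM factors of 0.994 for the embryo proper, 0.832 for the suspensor and 1.21 for the seed coat parenchyma, and expressed as CPM, the number of reads for each 1000000 scaled reads. Gene models with a mean of at least 5 CPM over the 3 libraries (19940 gene models) were compared on the log2(CPM + 1) scale, which understates the change of low genes, and a difference of at least 4-fold was taken as the size to count. Ratios of named genes are ratios of scaled counts, with 95% intervals from the exact Clopper-Pearson interval of 1 library's share of the gene's reads in both. A gene with 0 reads in a library is set at the floor of 3 reads in that library and its fold is given as a lower bound at that floor. The lower end of its counting interval lies below that fold and is given beside it. A gene with 1 to 3 reads keeps the ratio of its own counts with the wide interval these give, so the ratios of such genes are not on the scale of the bounds. Shares of a library's reads have 95% Wilson intervals. Detection was counted at 1 CPM or more and at least 3 reads, with CPM taken on the unscaled library total. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots were drawn with matplotlib 3.10.9.

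The genes to be named were chosen by a rule written before the data were examined. Within each comparison they are the gene models with the largest log2 ratio in each direction, among those with at least 50 reads in the higher library and a lower interval bound above 4-fold, limited to 2 per direction because no names are available. Other settings chosen beforehand were DESeq2 (version 1.42.0) size factors, upper-quartile scaling, unscaled totals, totals without the 50 most abundant genes, other CPM minimums, other fold sizes, other added constants, an interval bound in place of the ratio, and thinning every library to 8365831 reads. The same settings could not be applied to the gene lists.

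The steps were tested on simulated data, in which Poisson counts were drawn from the mean of the real libraries and 200 gene models were changed by a known fold, 50 for each of 4 fold sizes. In the simulated comparison of embryo proper with suspensor, over 19962 gene models, 100% of the 8-fold and 16-fold changes, 38% of the 4-fold changes and 0% of the 2-fold changes were counted, with 0 counted among unchanged gene models. The share of 4-fold changes counted was 30% for suspensor with seed coat parenchyma and 16% for embryo proper with seed coat parenchyma. These simulations hold counting error only. Only 200 gene models were changed from a common mean, so libraries as unlike as the real ones were not simulated. The 0 counted among unchanged gene models therefore does not cover errors that scaling may bring.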

Results

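Gene expression was profiled in 3 compartments of the developing soybean seed. The embryo proper is the part of the young embryo that goes on to form the seedling, and the suspensor is the short-lived stalk that anchors it and connects it to the maternal tissue. Both were captured at the globular stage, before cotyledons form. The seed coat parenchyma is a layer of the maternal tissue around the embryo, and it was captured at the later, early maturation stage. Each compartment was represented by 1 library, so that no value below has a replicate, and differences were judged against counting error only. The libraries held 11603055 assigned reads for the embryo proper, 8365831 for the suspensor and 11894273 for the seed coat parenchyma. A level of 1 CPM on these unscaled totals, as used for detection, stood for 11.6, 8.37 and 11.9 reads. The levels of single genes and the comparisons used TMM-scaled CPM. On that scale the floor of 3 reads set for a count of 0 stood for 0.260, 0.431 and 0.209 CPM, in the same order. The upper bound of the counting interval for a count of 0 was higher, at 0.320, 0.530 and 0.256 CPM.

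The fewest genes were detected in the suspensor library and the most in the seed coat parenchyma library. At 1 CPM or more, 21513 gene models were detected in the suspensor, 24350 in the embryo proper and 27859 in the seed coat parenchyma. After all libraries were thinned to the depth of the suspensor library, the numbers were 21513, 24264 and 27678, in the same order. The minimum of 1 CPM scales with the total, so thinning could hardly change these numbers. Of the 66210 gene models, 23296 had at least 1 read in all 3 libraries and 27197 had none in any. Reads in the seed coat parenchyma alone were found for 5646 gene models, against 1759 for the embryo proper alone and 1114 for the suspensor alone. These patterns count single reads in the full libraries, so they depend on the unequal depths. Highly expressed genes were similar in number, with 1715 gene models at 100 CPM or more in the embryo proper, 1554 in the suspensor and 1755 in the seed coat parenchyma. At 1000 CPM or more the numbers were 63, 68 and 50.

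The transcript pool of the suspensor was also the most concentrated. Its 10 most abundant gene models took 18.52% of all reads (95% Wilson interval 18.50 to 18.55%), compared with 13.08% (13.06 to 13.10%) in the embryo proper and 8.62% (8.60 to 8.63%) in the seed coat parenchyma. The 50 most abundant took 26.4%, 19.6% and 15.6%. The most abundant gene models that together made up 50% of the reads numbered 626 in the suspensor, 967 in the embryo proper and 1681 in the seed coat parenchyma.

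**Figure D1:**
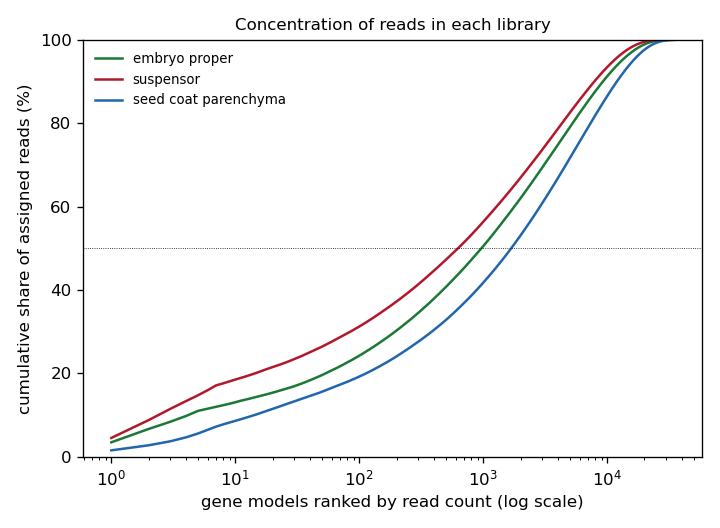
Cumulative share of assigned reads (%) against gene models ranked by read count (log scale), 1 line per library; the dotted line marks 50%. The line of the suspensor lies above the others over most of the range and reaches 50% at 626 gene models, against 967 for the embryo proper and 1681 for the seed coat parenchyma.

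The first comparison asked how the 2 regions of the globular embryo differ in gene activity. Among 19940 gene models compared, 3028 were 4-fold or more higher in the embryo proper and 2791 were 4-fold or more higher in the suspensor, together 29.2% of those compared. A difference of under 2-fold was found for 8712 gene models (43.7%). Genes high in the suspensor carried more of its transcript pool than genes high in the embryo proper did of theirs. The 2791 suspensor-high gene models took 33.9% of suspensor reads and 3.13% of embryo proper reads, while the 3028 embryo proper-high gene models took 20.3% of embryo proper reads and 2.13% of suspensor reads. On the log2(CPM + 1) scale, differences of 100-fold or more were found for 25 gene models on the suspensor side and 3 on the embryo proper side.

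On the log2(CPM + 1) scale, the largest differences on the suspensor side were in Glyma13g41990, on chromosome 13, and Glyma20g26030, on chromosome 20. Glyma13g41990 stood at 619 CPM in the suspensor (4308 reads) and 1.30 CPM in the embryo proper (15 reads), a ratio of 476 (counting interval 288 to 851). Glyma20g26030 stood at 901 CPM in the suspensor and 2.43 CPM in the embryo proper, a ratio of 371 (257 to 559). Both had 0 reads in the seed coat parenchyma. On the embryo proper side the largest differences were in Glyma20g24940, on chromosome 20, and Glyma11g07710, on chromosome 11. Glyma20g24940 stood at 188 CPM in the embryo proper and 0.575 CPM in the suspensor (4 reads), a ratio of 327 (128 to 1203). Glyma11g07710 stood at 154 CPM in the embryo proper and had 3 reads in the suspensor, a ratio of 358 (122 to 1736). These embryo proper genes, too, had 0 reads in the seed coat parenchyma.

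Most of these counted differences were larger than counting error. The lower bound of the counting interval was itself 4-fold or more for 2600 of the 3028 gene models higher in the embryo proper and for 2469 of the 2791 higher in the suspensor. The share of gene models differing by 4-fold was 34.4% at a mean of 5 to 10 CPM and 23.2% at 100 CPM or more. Which side was the larger depended on the settings: the suspensor side was the larger with DESeq2 size factors (2817 against 3037), at a mean of 20 CPM or more (1068 against 1313) and with a larger added constant of 5 CPM (1485 against 1668).

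**Figure D2:**
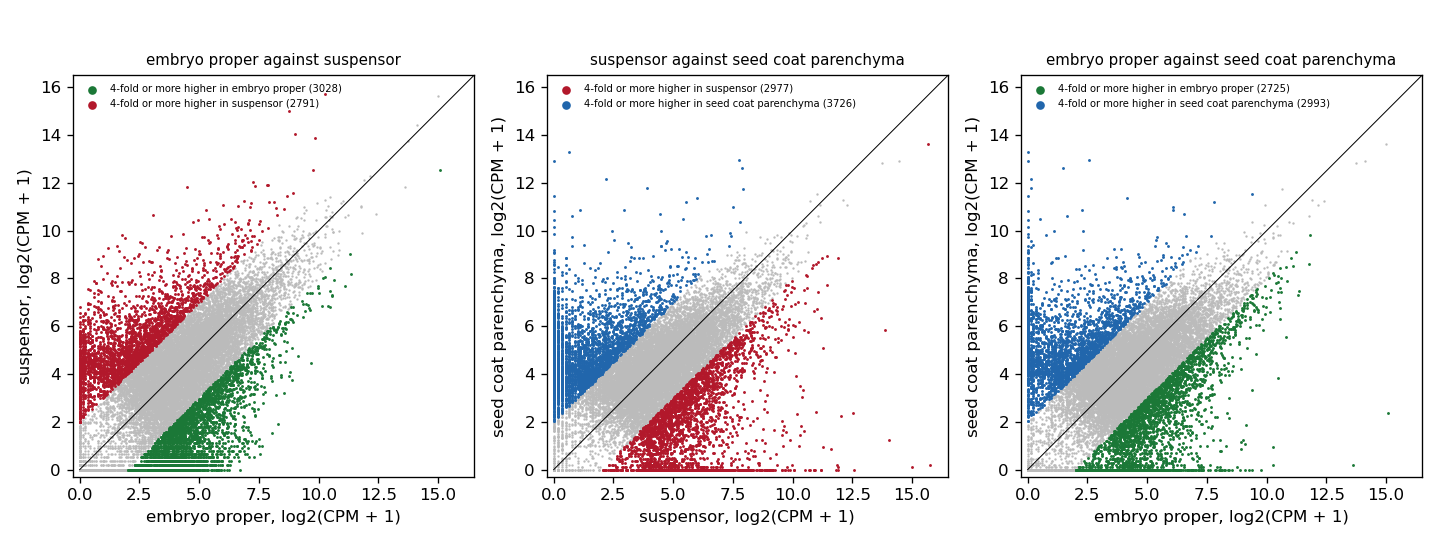
Each panel plots the log2(CPM + 1) of 19940 gene models in 1 library against another; coloured points are 4-fold or more higher in the named library, grey points are not, and the black line marks equal levels. The numbers of coloured gene models are 3028 and 2791 for the embryo proper and suspensor, 2977 and 3726 for the suspensor and seed coat parenchyma, and 2725 and 2993 for the embryo proper and seed coat parenchyma.

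The second comparison set the suspensor against the seed coat parenchyma, a maternal tissue. It differed also in developmental stage, section thickness and instrument, and none of these can be told apart from tissue. In the suspensor, 2977 gene models were 4-fold or more higher, and 3726 were 4-fold or more higher in the seed coat parenchyma, together 33.6% of those compared. The suspensor-high gene models made up 45.9% of the suspensor's reads and 5.08% of the seed coat's, and the seed coat-high gene models made up 30.8% of the seed coat's reads and 1.09% of the suspensor's. Of the seed coat-high gene models, 1069 had 0 reads in the suspensor, and of the suspensor-high gene models 601 had 0 reads in the seed coat parenchyma. These numbers are not matched for depth. The floor for a count of 0 was 0.431 CPM in the suspensor and 0.209 CPM in the seed coat parenchyma.

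The largest suspensor-side differences were again ranked on the log2(CPM + 1) scale. With almost no reads in the seed coat parenchyma, that ranking follows the level in the suspensor. The high levels there are therefore no separate result. Glyma10g41250, on chromosome 10, stood at 54324 CPM in the suspensor, 1218 CPM in the embryo proper and had 2 reads in the seed coat parenchyma, a suspensor to seed coat ratio of 390788 (counting interval 108181 to 3226878). Glyma20g26010, on chromosome 20, stood at 32646 CPM in the suspensor, 436 CPM in the embryo proper and had 1 read in the seed coat parenchyma, a ratio of 469696 (84300 to 18552063). On the other side, Glyma09g01320, on chromosome 9, stood at 7654 CPM in the seed coat parenchyma and had 0 reads in the suspensor. It was at least 17752-fold higher in the seed coat when the suspensor is set at 3 reads. The lower end of its counting interval was 14437-fold. Glyma06g02500, on chromosome 6, stood at 10026 CPM in the seed coat parenchyma and 0.575 CPM in the suspensor (4 reads), a ratio of 17440 (6811 to 64010).

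The balance between the sides depended on scaling and on abundance. The suspensor side held 44.4% of the 4-fold differences with TMM scaling and 30.2% (2154 against 4973) with unscaled library totals. Among gene models with a mean of 20 CPM or more the balance turned, with 1601 higher in the suspensor and 1135 higher in the seed coat parenchyma.

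The third comparison set the embryo proper against the seed coat parenchyma, with the same differences in stage, section thickness and instrument. In the embryo proper, 2725 gene models were 4-fold or more higher, and 2993 were 4-fold or more higher in the seed coat parenchyma, together 28.7% of those compared. Embryo proper-high gene models took 31.1% of embryo proper reads and 3.97% of seed coat reads. Seed coat-high gene models took 29.8% of seed coat reads and 1.36% of embryo proper reads. On the log2(CPM + 1) scale, differences of 100-fold or more were found for 67 gene models on the embryo proper side and 146 on the seed coat side.

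The embryo proper side was led by Glyma19g42940, on chromosome 19, and Glyma02g13210, on chromosome 2. Glyma02g13210 stood at 34902 CPM in the embryo proper, 5854 CPM in the suspensor and 4.17 CPM in the seed coat parenchyma, an embryo proper to seed coat ratio of 8369 (6502 to 10967). Glyma19g42940 stood at 12363 CPM in the embryo proper, 3677 CPM in the suspensor and had 2 reads in the seed coat parenchyma, a ratio of 88938 (24620 to 734398). The seed coat side was led by the same gene models as against the suspensor. Glyma06g02500 and Glyma09g01320 both had 0 reads in the embryo proper and were at least 38546-fold and 29426-fold higher in the seed coat parenchyma, with the embryo proper set at 3 reads. The lower ends of their counting intervals were 31348-fold and 23931-fold. With unscaled totals the embryo proper side held 37.6% of the 4-fold differences (2225 against 3695) instead of 47.7%, with upper-quartile scaling it became the larger (2982 against 2811), and among gene models with a mean of 20 CPM or more it was the larger too (1507 against 1098).

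Across all 3 compartments, 1389 gene models were 4-fold or more higher in the suspensor than in both others, 974 in the embryo proper and 1822 in the seed coat parenchyma. At a mean of 20 CPM or more the numbers were 704, 431 and 637, so that the seed coat set was then smaller than the suspensor set. In its own library each set had a median of 53.5 CPM (suspensor), 43.5 CPM (embryo proper) and 36.7 CPM (seed coat) with TMM scaling, but of 44.5, 43.3 and 44.4 CPM on unscaled totals. Members at 1000 CPM or more numbered 43, 12 and 20 with TMM scaling and 34, 12 and 25 on unscaled totals. The suspensor set took 28.27% of suspensor reads (95% Wilson interval 28.24 to 28.30%), 2.27% of embryo proper reads and 1.27% of seed coat reads. Without its 2 largest members it took 21.0% of suspensor reads. The embryo proper set took 12.97% of embryo proper reads (12.95 to 12.99%) and 9.24% without its 2 largest members. The seed coat set took 23.32% of seed coat reads (23.29 to 23.34%) and 21.1% without its 2 largest members. With the 2 largest members of each set left out, the suspensor share was thus close to that of the seed coat set. It remained above that of the embryo proper set. The reads of the members left out stayed in the library totals. In the seed coat set, 441 of the 1822 members had 0 reads in both embryo regions. Of the suspensor set, 39 members had 0 reads in both other libraries, and of the embryo proper set 25. These numbers with 0 reads come from libraries of unequal depth and were not matched for it. Here too, stage, section thickness and instrument of the seed coat library cannot be told apart from tissue.

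**Figure D3:**
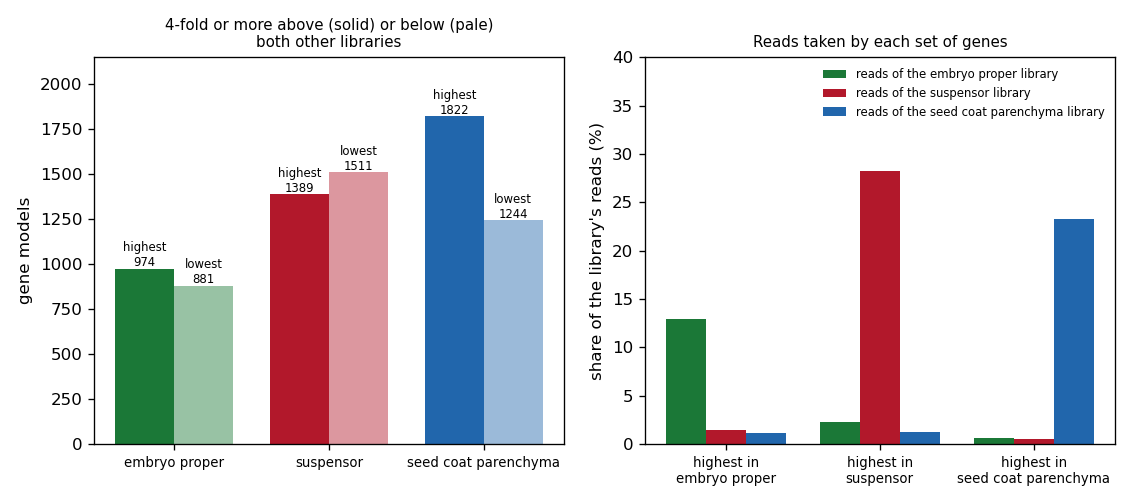
Left, number of gene models 4-fold or more above (solid bars) or below (pale bars) both other libraries. Right, share of each library's reads (%) taken by the 3 sets of gene models highest in 1 library; the suspensor set takes 28.3% of suspensor reads, the seed coat set 23.3% of seed coat reads and the embryo proper set 12.97% of embryo proper reads.

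Genes were also set apart by a lower level in 1 compartment. In the suspensor 1511 gene models were 4-fold or more below both other libraries, 338 of them with 0 reads there. In the seed coat parenchyma 1244 gene models were 4-fold or more below both embryo regions, 363 of them with 0 reads there, and the 1244 took 14.7% of embryo proper reads, 25.9% of suspensor reads and 0.991% of seed coat reads. Of these, 247 also belonged to the suspensor set and 65 to the embryo proper set. The other 932 took 9.09% of embryo proper reads, 7.53% of suspensor reads and 0.934% of seed coat reads. In the embryo proper 881 gene models were 4-fold or more below both others, 140 of them with 0 reads there. The numbers with 0 reads were not matched for depth, and a count of 0 stood for a higher floor in the suspensor than elsewhere. A spread of under 2-fold across all 3 libraries was found for 3597 gene models (18.0%).

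Across genes, which are not independent replicates, the 2 embryo regions had the highest correlation. Over 19940 gene models the Spearman correlation was 0.49 (Pearson 0.53) between embryo proper and suspensor, 0.33 (Pearson 0.32) between embryo proper and seed coat parenchyma, and 0.26 (Pearson 0.22) between suspensor and seed coat parenchyma. The minimum on mean abundance sets the size of these values, and their order was the same at each minimum tried. The seed coat library differed also in stage, section thickness and instrument, so the order cannot be assigned to tissue alone.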

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

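All alternatives were planned before the data were examined, except the removal of unplaced scaffolds, the counting of runs of adjacent gene models once, and the thinning outside the 50 most abundant genes. No paired analysis was possible because each region has 1 library. The planned gene list alternatives were not run, since no identifier could be paired with a name. Of 117 alternative values of counts and correlations, 38 moved beyond 1.5 times the count or beyond the interval of the correlation. Some could not move, such as a Spearman correlation with a larger added constant. Others changed what was counted, such as other fold sizes, so this tally does not measure stability. The numbers of 4-fold genes are given here in the order embryo proper and suspensor (first comparison), suspensor and seed coat (second), embryo proper and seed coat (last). With a minimum mean of 20 CPM they were 1068 and 1313, 1601 and 1135, and 1507 and 1098, because fewer genes were compared. At 2-fold they were 5754 and 5474, 5717 and 6082, and 5827 and 5473. At 8-fold they were 1458 and 1399, 1697 and 2405, and 1230 and 1804. With 5 CPM added they were 1485 and 1668, 2020 and 2220, and 1560 and 1911. With no abundance minimum the seed coat side numbered 6340 in the second and 4969 in the last comparison. Every other scaling, thinning, the interval bound and the smaller constant kept the numbers within 1.5 times. Unscaled totals shifted the median log2 ratio of all genes to 0.23, -0.54 and -0.25, and totals without the 50 most abundant genes shifted it to 0.11, -0.33 and -0.16, from 0.00, 0.02 and 0.05 with TMM; the direction of genes with a ratio smaller than these shifts depends on that choice. The numbers of genes highest in 1 library became 1558 (embryo proper) and 3421 (seed coat) with no minimum, 431, 704 and 637 (embryo proper, suspensor, seed coat) at 20 CPM, and 355 and 698 (embryo proper, suspensor) at 8-fold. The set of the seed coat was therefore larger than that of the suspensor at 5 CPM and smaller at 20 CPM. Spearman correlations were 0.35, 0.10 and 0.19 at 20 CPM and 0.73, 0.57 and 0.62 with no minimum, in the order of the comparisons. Named genes were chosen for their large ratios, so their direction could not turn under these settings, but their size moved: with 5 CPM added the log2 ratio of Glyma20g24940 between embryo proper and suspensor was 5.12 instead of 6.91. The floor of 3 reads set for a gene with 0 reads stood for 0.209 CPM (seed coat) to 0.431 CPM (suspensor) on the TMM scale. The amplification from 3 to 5 ng of RNA adds variation that 1 library per region cannot measure.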

Other observations

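The cross-capture tests were chosen after the ratios had been seen, and the other tests before their results were seen. For gene models 2 places apart no outcome had been set beforehand. A small group of genes was abundant everywhere. The gene models at 1000 CPM or more in all 3 libraries numbered 11 and took 8.71% of embryo proper reads, 8.91% of suspensor reads and 4.96% of seed coat reads, and without the largest of them in each library 5.51%, 4.63% and 3.42%. Glyma20g26010 and Glyma20g26030, both among the gene models named for the suspensor, lie 2 places apart in the identifier order of chromosome 20. The gene model between them had 0 reads in all 3 libraries.

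The suspensor library detected fewer genes than the embryo proper library. At a minimum of 1 CPM, lower depth is argued against as the whole cause, since after thinning to equal totals the suspensor reached only 88.7% of the embryo proper number. This minimum scales with the total, so thinning could hardly change the numbers (24350 to 24264 in the embryo proper). Detection at a fixed number of reads is therefore not covered. Reads taken from the rest by the 50 gene models of highest mean CPM over the libraries are argued against as the whole cause too. After thinning to equal reads outside these 50 the value was 89.7%, where 95% had been set as the mark. Totals without them still left a median log2 ratio of 0.11 between embryo proper and suspensor, against 0.23 with unscaled totals. A larger group of genes abundant in the suspensor is therefore not covered. Random loss of RNA molecules before amplification stays open. Among genes at 20 to 50 CPM in both other libraries 0.492% (Wilson interval 0.249 to 0.967%) had 0 reads in the suspensor and 0.256% (0.0997 to 0.657%) in the embryo proper, while at 5 to 10 CPM the shares were 6.87% (5.43 to 8.66%) and 2.17% (1.36 to 3.44%). In the seed coat parenchyma, which had the most genes detected, the shares were 1.51% (1.00 to 2.28%) at 20 to 50 CPM and 1.63% (0.935 to 2.83%) at 5 to 10 CPM. Each library's share comes from a different set of genes, so these shares do not measure technical loss alike. A truly narrower gene repertoire of the suspensor may give the same values.

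Genes of 1 embryo region were often found at a low level in the other, and a candidate explanation is RNA of the neighbouring region captured in the cut. The gene models used here were chosen as 4-fold or more higher in 1 library. That choice alone keeps their level in the other region low and limits the upper end of the ratios. A single fixed share of foreign RNA would put all such genes at 1 ratio. Across the 420 gene models highest in the suspensor and at 100 CPM or more there, the level in the embryo proper was 8.30% of the suspensor level at the median and 0.842% at the 10th percentile, and the 90th percentile was 24.0 times the 10th. Across the 215 gene models highest in the embryo proper, the level in the suspensor was 12.6% at the median and 1.24% at the 10th percentile, a spread of 17.6 times. A fixed share therefore cannot be the whole source. Such a share would also put a floor under every gene. In the embryo proper 13 of the 420 gene models had an upper counting bound, at 95% adjusted for the number of genes, below the 10th percentile, and in the suspensor 0 of the 215 did. That percentile comes from these same ratios, so these numbers are no separate evidence. The lowest such bound was 0.498% in the embryo proper (8 reads, against 3080 in the suspensor). In the suspensor it was 1.26% (0 reads, against 1199 in the embryo proper), not below the 10th percentile there. A smaller share, own expression of these genes in both regions, and for the suspensor also a share of the size of its 10th percentile, stay open.

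Gene models highest in the same library were tested for lying next to each other. There were 162 such adjacent pairs on the chromosomes, against a median of 121 and a highest value of 152 in 1000 random placements among the compared genes, which argues against chance placement for the 3 sets pooled. By set, the seed coat had 87 pairs (central 95% of placements 50 to 80, highest 87) and the suspensor 52 (26 to 49, highest 60), while the 23 pairs of the embryo proper lay within chance (11 to 27). At 2 places apart there were 142 pairs, above the central 95% of placements (94 to 135), and at 3 to 5 places apart there were 347, within it (306 to 373). A single transcript annotated as 2 gene models may give pairs that are adjacent. The outcome set beforehand for it was no excess at 3 to 5 places apart, and none was found, which does not single out this explanation. It would also give no excess at 2 places, a mark not set beforehand. The 142 pairs there lay above the central 95% but below the highest placement of 146. For the adjacent pairs this explanation therefore stays open. Shared reads or shared regulation of tandem gene copies were not tested.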
